A study of Candida albicans with 4 samples.

How the data were processed

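Expression in *Candida albicans* strain SC5314 was measured on 4 2-colour spotted arrays, each of which carried RNA from cells exposed to monoclonal antibody C7 in one dye and RNA from untreated cells in the other. Per the labels' protocols, an overnight culture was diluted to an OD600 of about 0.1 and split, C7 was added to one part at 12.5 µg/ml, and both parts were kept at 37 °C for 18 h. RNA was extracted with Trizol, and 15 µg per channel was reverse-transcribed with a primer mix specific for the species in the presence of Cy5-dCTP or Cy3-dCTP. The C7 RNA carried Cy5 on arrays 1 and 3 and Cy3 on arrays 2 and 4, per the labels. All 4 arrays form 1 group, C7-exposed against untreated, and the array number is the replicate number in the labels. The labels call the arrays biological replicates 1 to 4, whereas the series' design text describes an experiment that was done and then repeated once, with swapped dyes. Which arrays share an extract is not given in the sources used here, so 4 arrays entered the fit, and p-values may partly measure technical spread.

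The deposited scanner files hold unnormalized intensities, per the file headers: the mean and median foreground and the median local background of each spot at 635 nm (Cy5) and 532 nm (Cy3). The deposited files also give, per the file headers, the percent of a spot's pixels brighter than the background plus 2 SD, and a quality code for each spot. The scanner and image software are not given in the sources used here. A second deposited table holds the authors' log2 ratio per spot and array. Set against the scanner files, these values equalled the log2 ratio of background-subtracted medians within 0.01 for 100 percent of values, with the sign turned on arrays 2 and 4, so that they run as C7-exposed over untreated. Their medians were 0.08, 0.15, 0.75 and −0.14 on arrays 1 to 4. Scale and sign of these ratios are therefore known, and the values are not centred. They served as an alternative.

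Intensities were read in R 4.3.3 and processed with limma 3.58.1. Background was corrected with normexp (offset 50) on mean foreground and median background, and each array was normalized by global loess with control spots and spots with a quality code below 0 at weight 0. Spots with a code below 0 were left out. Codes were −100, −75 and −50, and −75 was carried by 812 to 816 spots of each array. Each array had 13440 spots. Control, empty and missing spots aside, the names comprised 5879 numbered probes and 12 mitochondrial genes. Spots of one name were averaged. A probe was tested when it had a value on all 4 arrays and, in at least 1 channel on at least 2 arrays, at least 50 percent of its pixels above the background plus 2 SD. This left 5772 probes, 5760 numbered and 12 mitochondrial. Of the others, 98 lacked a value on an array and 21 were too dim. Control, empty and unprinted spots were not tested. Median foreground over median background lay between 6.74 and 9.14 in Cy5 and between 2.99 and 6.24 in Cy3. The number of arrays limits the precision.

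The log2 ratio of each probe was fitted with lmFit and eBayes, with 1 term for C7 (+1 where C7 RNA was in Cy5, −1 where it was in Cy3) and 1 for the dye, leaving 2 residual degrees of freedom before moderation. P-values were adjusted by Benjamini-Hochberg over the probes tested, with a threshold of 0.05. Errors of fitted values are limma's moderated SE. Probes at least 1.5-fold from 0 in the same direction on all 4 arrays were counted without a test. The rule for naming genes was the 12 highest and 12 lowest of the probes past the threshold with one sign on all arrays, filled with named genes of the lowest p, up to 4 members of each gene list, and 12 fixed genes including ALS3 and ENO1.

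Most of that rule was not applied. The numbered probes carry only numbers, with a CandidaDB number each. Of 5879, 0 matched a locus tag, synonym or accession among the 6263 genes of the RefSeq table for assembly ASM18296v3. Names and CandidaDB numbers were compared as written, with no prefix added, no suffix removed and synonym fields not split. Matches in another format were not sought, so the 0 does not show that these genes lack an entry. None of the 31 gene lists fixed before the data were examined (iron uptake, respiration, glycolysis, hyphal growth, cell wall, stress, ribosome and others, among which the iron lists were chosen knowing the study's interest in iron) had a member named in the files, and 0 of the 12 fixed genes did. The list tests were therefore not run, and at most 2 numbered probes are named in each direction, those with the lowest p. Control spots aside, the genes named in the files are mitochondrially encoded: NAD1 to NAD6, COB, COX1, Cox 2, COX3a, COX3b and ATP6. This list was chosen after the probe names, and before the values, had been seen. It was tested with camera (preset correlation 0.01, and estimated), and with fry.

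The fit was tested on simulated log ratios of the 5772 probes. Each variance was drawn from limma's fitted prior, the fitted dye effects were kept, and the noise was independent between arrays and probes. In the simulation, 200 probes were given a change of 1 or 2 on the log2 scale, in either direction. Of these, 94 percent of changes of 1 and 100 percent of changes of 2 were called, and 18 unchanged probes were called. The simulation held no print-block pattern and no wider spread at large changes. With 200 true changes the Benjamini-Hochberg threshold is also easier to pass than with few, and the real arrays gave 2 calls. These shares therefore do not give the power on the real arrays. On those, a probe at a log2 fold change of 3.12 was not called. Doubling the C7 channel of 200 probes in the scanner values moved their estimate by a median of 1.02. Alternatives covered background correction, foreground summary, normalization, filters, dye term, pairing of arrays, moderation, array weights, the authors' ratios, leaving out each array, and thresholds. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.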

Results

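The transcript response of *Candida albicans* strain SC5314, the reference strain of this pathogenic yeast, was measured after 18 h with monoclonal antibody C7, which is known to bind the cell-surface adhesin Als3 and enolase. C7 was given at 12.5 µg/ml, described by the submitters in one place as below the inhibitory level and in another as limiting growth without killing. Each of 4 spotted arrays compared RNA of C7-exposed cells directly with RNA of untreated cells of a split culture, with the dyes exchanged on arrays 2 and 4. Signal stood above background for 98.2 to 99.3 percent of probes in Cy5 and for 92.7 to 99.1 percent in Cy3, the lowest share being that of Cy3 on array 3. Of the 5772 probes tested, the 12 for mitochondrially encoded genes carry gene names in the files, and the other 5760 are known here only by number.

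To find which transcripts responded to C7, each of 5772 probes was tested over the 4 arrays. With the 4 arrays as replicates, 2 probes rose and 0 fell past the threshold (limma, Benjamini-Hochberg adjusted p below 0.05), while 377 probes had an unadjusted p below 0.05, 168 higher and 209 lower, where chance alone gives 288.6. Probe 5522.1 (CandidaDB number CA3740) rose 3.22-fold, with a log2 fold change of 1.69 ± 0.11 (SE, n = 4 arrays; limma adjusted p = 0.0144). Its log2 ratio was 1.56, 1.63, 1.60 and 1.97 on arrays 1 to 4. Probe 12102.2 (CA2556) rose 3.34-fold, with a log2 fold change of 1.74 ± 0.13 (SE, n = 4 arrays; limma adjusted p = 0.0267), and was higher on 4 of 4 arrays. Larger mean differences were measured with more spread between arrays. The highest mean, an 8.68-fold higher level in C7-exposed cells, had a log2 fold change of 3.12 ± 0.36 (SE) and did not pass (limma adjusted p = 0.0898). The probe with the next highest mean was 7.28-fold higher, also without passing (limma adjusted p = 0.0676).

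Counted without a test, 8 probes were at least 1.5-fold higher in C7-exposed cells on all 4 arrays and 3 were at least 1.5-fold lower. At 2-fold the counts were 5 higher and 0 lower. Over arrays 2 to 4 alone, without array 1, 10 probes were at least 1.5-fold higher and 35 lower, so that the balance of directions rests on array 1. Below 0, the lowest p belonged to probe 1222.2 (CA4836), at a log2 fold change of −1.08 ± 0.13 (SE, n = 4 arrays), and to probe 14364.1 (CA4399), at −0.997 ± 0.122, both with a limma adjusted p of 0.0898. The value of 14364.1 was −0.37 ± 0.20 when loess was fitted within each print block, whereas 1222.2 stayed at −1.04 ± 0.15. The lowest mean of all probes, −1.11 ± 0.21 (SE), did not pass either (limma adjusted p = 0.233). Both calls of a rise ended (0 probes) with loess per print block, without array 1, without array 3, and with the authors' ratios centred on each array's median, where limma gave 545, 647, 418 and 254 probes at an unadjusted p below 0.05 and the log2 fold change stayed between 1.66 and 1.70 for 5522.1 and between 1.63 and 1.84 for 12102.2. Averaging the arrays as dye swaps of shared extracts gave 10 probes (9 higher, 1 lower) when arrays 1 and 2 and arrays 3 and 4 were paired. It gave 41 (21 higher, 20 lower) when arrays 1 and 4 and arrays 2 and 3 were. With loess per print block as well these became 0 (331 at an unadjusted p below 0.05, limma) and 299 (140 higher, 159 lower). The second pairing averages arrays 1 and 4, whose log2 ratios correlated at −0.38, and at −0.28 with loess per print block. With that loess, r was 0.27 between arrays 1 and 2, 0.39 between 3 and 4, and 0.24 between 2 and 3. With global loess, the undiluted EFT3#1 control spots gave log2 ratios of 0.92, 0.58, −0.40 and −0.65 on arrays 1 to 4. In the contrast of arrays 1 and 2 against 3 and 4, 70 probes were beyond 1.5-fold, and 1 in that of 1 and 4 against 2 and 3. All these values go against a shared extract of arrays 1 and 4, and so against the counts of 41 and 299, but do not exclude it. Because the true pairing is not given, the number of responding transcripts is not settled and the p-values may partly measure technical spread.

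**Figure D1:**
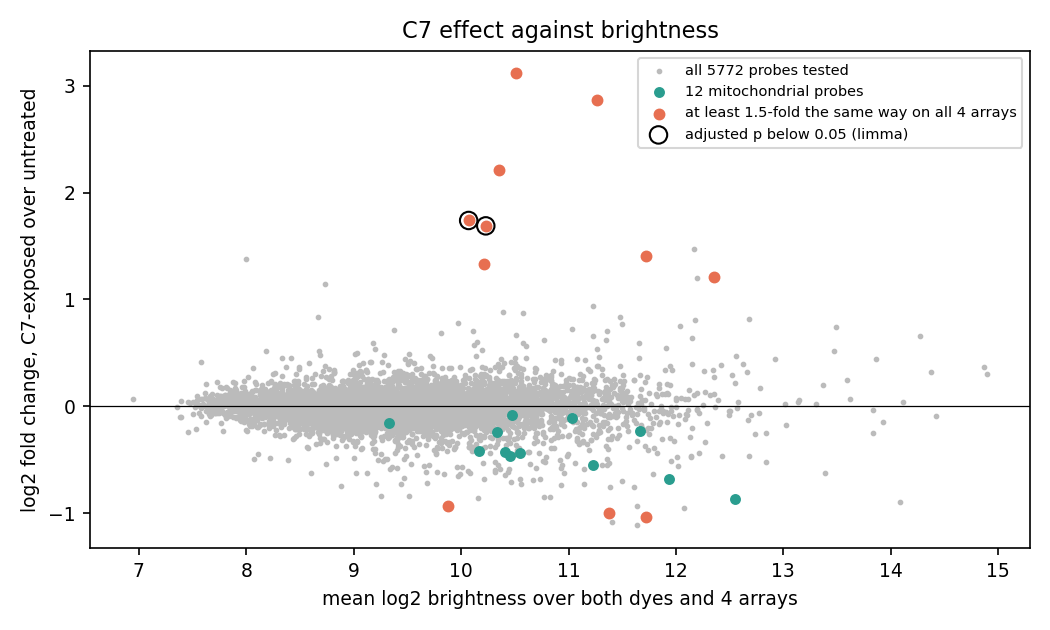
The log2 fold change of C7-exposed over untreated cells (y axis) is plotted against mean log2 brightness over both dyes and 4 arrays (x axis), 1 point per probe for 5772 probes, with mitochondrial probes, probes at least 1.5-fold from 0 on all 4 arrays, and the 2 probes past the adjusted threshold marked. Most probes lie near 0, 8 of the marked 1.5-fold probes lie above it and 3 below, and the 12 mitochondrial probes all lie below 0.

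All 12 probes for genes carried by the mitochondrial genome had a log2 fold change below 0, and 7 were below 0 on each of the 4 arrays. As a group they passed camera with a preset correlation of 0.01 (p = 1.77e-11), but not with an estimated correlation (p = 0.0783 with an estimated correlation). Their median was −0.42, or 1.34-fold higher in untreated cells, against a median of −0.0016 for all probes. The mean over the 12 genes was −0.53, −0.50, −0.28 and −0.24 on arrays 1 to 4, giving −0.39 ± 0.15 (SD, n = 4 arrays). No gene passed over all probes, and 7 of the 12 passed when adjusted over the list alone, a list chosen after the probe names were seen. These 7 were COB, COX1, COX3a, COX3b, NAD1, NAD2 and NAD6. Pairing arrays 1 with 4 and 2 with 3 changed this, with COB and COX1 passing over all probes (limma adjusted p = 0.0211 and 0.0457), and all 7 passing with loess per print block as well. That pairing averages arrays 1 and 4, which correlated at −0.38. If arrays 1 and 2 share extracts, it leaves the spread between experiments out of the error. Under the other pairing, 1 with 2 and 3 with 4, none of the 12 passed (COB 0.0906 and COX1 0.333, limma adjusted p), nor with loess per print block as well (0.844 and 0.575).

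COB, which encodes cytochrome b of respiratory complex III, had the lowest value, a log2 fold change of −0.87 ± 0.11 (SE, n = 4 arrays; limma adjusted p over all probes = 0.108) that was below 0 on 4 of 4 arrays. It was −0.52 ± 0.12 with loess per print block. Among the cytochrome c oxidase (complex IV) genes, COX1 stood at −0.68 ± 0.16, COX3a at −0.55 ± 0.12 and COX3b at −0.43 ± 0.10, all below 0 on 4 of 4 arrays. The probes COX3a and COX3b were named for the same subunit and cannot be taken as independent. Cox 2 stood at −0.114 ± 0.107 (limma adjusted p = 0.974) and at −0.029 with loess per print block. Among the genes of NADH dehydrogenase (complex I), NAD6 stood at −0.46 ± 0.12, NAD2 at −0.44 ± 0.15 and NAD1 at −0.42 ± 0.12, and NAD5, NAD4 and NAD3 at −0.24 ± 0.13, −0.16 ± 0.11 and −0.08 ± 0.13. ATP6, a subunit of ATP synthase, stood at −0.23 ± 0.10, and at −0.076 with loess per print block.

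The estimated correlation between the 12 genes was 0.32. By fry, which asks whether the genes moved one way without comparing them with others, p was 0.0432. Over the 4 array means, an exact two-sided sign-flip test cannot give a p below 0.125, its value here. The authors' ratios, which are not centred and whose median C7 effect over all probes was 0.19, put Cox 2, NAD3 and NAD4 above 0 (0.091, 0.092 and 0.067), and the median of the 12 genes at −0.20. Without array 1, NAD3 stood at 0.056, NAD2 at −0.28 and NAD5 at −0.14. NAD5 stood at −0.13 without array 2, and NAD4 at −0.073 without array 4 and −0.24 without array 2. NAD3 ranged from −0.22 (without array 3) to 0.056, and Cox 2 from −0.19 (without array 1) to −0.041 (without array 3).

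**Figure D2:**
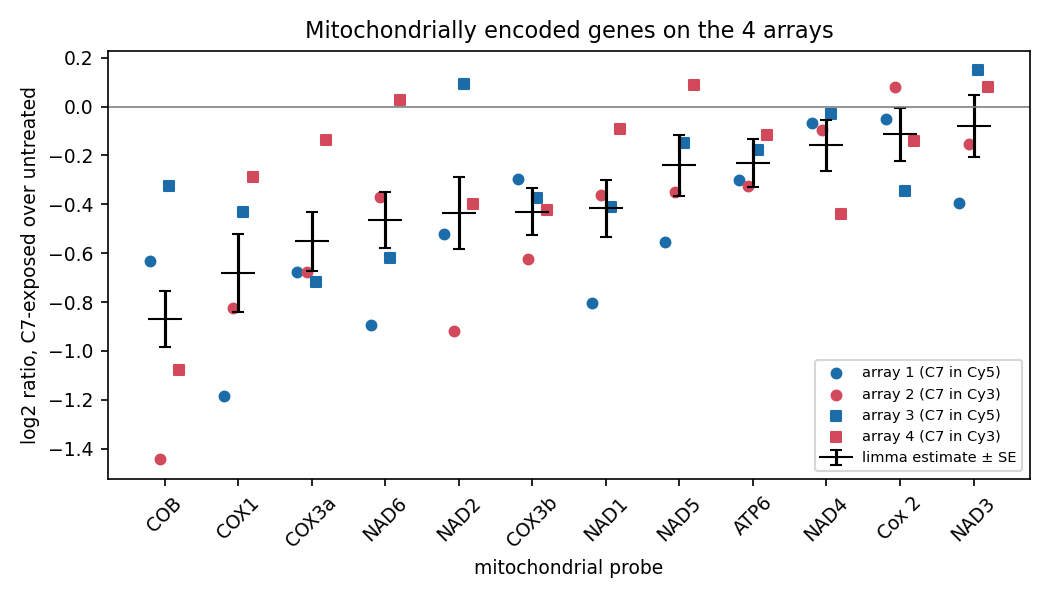
The log2 ratio of C7-exposed over untreated cells (y axis) is shown for 12 mitochondrially encoded genes (x axis), with 1 point per array coloured by the dye of the C7 RNA, and the limma estimate with its SE in black (n = 4 arrays). All 12 estimates lie below 0, from −0.87 for COB to −0.08 for NAD3, and the authors' uncentred ratios put Cox 2, NAD3 and NAD4 above 0.

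Whether C7 moved the genes of iron acquisition, in which the study was interested, or the genes of its known targets Als3 and enolase was not read. The numbered probes were matched to genes only by their names as written, without a match. No member of the 31 gene lists was named in the files.

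The arrays were also compared with each other, because the dye exchange is there to separate C7 from dye effects. Across 5772 probes, which are not independent replicates, the log2 ratios of C7-exposed over untreated cells correlated at r = 0.18 between arrays 1 and 3 and r = 0.45 between arrays 2 and 4, the pairs of the same dye orientation. Between arrays of opposite orientation r was −0.12 (1 and 2), −0.38 (1 and 4), 0.02 (2 and 3) and 0.09 (3 and 4). By the rule set for this comparison, a pair of arrays below −0.3 leaves the direction of the C7 effect unsettled. Arrays 1 and 4 met that rule with global loess, and the other pairs did not. The mean over the 6 pairs was 0.04. With loess per print block, r between arrays 1 and 2, 2 and 3, and 3 and 4 became 0.27, 0.24 and 0.39, while arrays 1 and 4 stayed below 0, at −0.28. No pair then lay below −0.3, so whether the rule was met depended on the normalization. No probe passed for a dye effect (limma, lowest adjusted p = 0.189), although 1186 probes had an unadjusted p below 0.05 for it, where chance alone gives 288.6. The dye effect had a larger SD over probes (0.225) than the C7 effect (0.189), so the lack of calls does not mean that no dye effect was present.

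**Figure D3:**
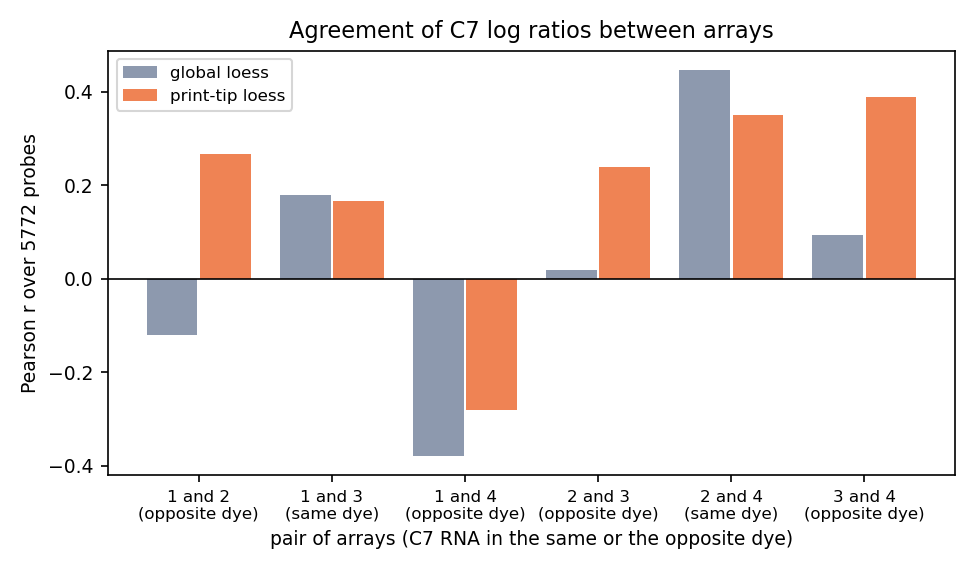
Pearson correlations across 5772 probes (y axis) of the log2 ratios of C7-exposed over untreated cells are shown as bars for each of the 6 pairs of arrays (x axis), with global loess and with loess per print block. Arrays 1 and 4 correlate below 0 with both (−0.38 and −0.28), and the other 5 pairs lie above 0 with loess per print block.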

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

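Tests of arrays 1 and 4 against a common dye effect, of the 12 mitochondrial genes against dye bias, and of other sign patterns were chosen only after the result was seen. An array standing apart from the other 3 was sought in 24 values, where chance gives about 1.2, and was found in 6. Probe 5522.1 had a log2 ratio of 1.97 on array 4. COX3a stood at −0.14 and NAD4 at −0.44 on array 4. Foreground over background in Cy5 was 9.14 on array 2, the share of probes above background in Cy3 was 92.7 percent on array 3, and 181 spots of probes carried a quality code below 0 on array 1, against 24 to 44 on the others.

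Signals also appeared in spots outside the comparison. Among control spots named for other organisms or reporter genes, 13 names were brighter than the 99th percentile of empty spots in all 8 channel readings. The undiluted EFT3#1 control spots had a median signal of 758, against 5 for empty spots. Of 153 names marked as missing, 1 was brighter than that percentile in all 8 readings.

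The pattern weighed first is that the 12 mitochondrially encoded genes all lay below 0. Their median was lower than that of each of 10000 random lists matched on brightness (percentile 0.01, the lowest that number can show), which argues against a brightness trend left by loess. The 69 neighbouring probes, in 4 blocks, had a median C7 effect of −0.014 (95% bootstrap interval −0.04 to 0.02), which argues against a place effect common to the group. A pooled median cannot show blocks biased in opposite directions. With loess per print block the median of the 12 genes stayed at −0.42, while COB moved from −0.87 to −0.52 and NAD2 from −0.44 to −0.49. The values of single genes therefore depended on the print-block correction. The mean of the 12 genes was −0.40 with C7 in Cy5 and −0.37 with C7 in Cy3, which argues against dye bias. A lower level of mitochondrial transcripts in C7-exposed cells is therefore a candidate explanation, as a hypothesis. A difference in RNA preparation or in the priming of these transcripts between the cultures was not tested and stays open, as does the inter-gene correlation of 0.32, with which the group did not pass.

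A further pattern is that arrays 1 and 4 moved against each other, at r = −0.38 across probes. A dye effect common to all arrays would, without a shared C7 response, put every pair of opposite orientation below 0. Arrays 3 and 4 correlated at 0.093 (SE 0.013 if probes were independent, which they are not). A dye effect alone therefore does not account for every pair. A shared C7 response would also raise r, so the part of dye in arrays 1 and 4 could not be settled. Dim probes are not the whole cause, since r was −0.40 over the brighter 50 percent of probes. Print blocks held 25.9 to 30.3 percent of the variance of log2 ratios on each array, and after print-tip loess r was −0.28, between the bounds set for and against, so position could not be told apart from other causes. A difference between experiments stays open: a term for arrays 1 and 2 against 3 and 4 passed for 0 probes (limma; 503 at an unadjusted p below 0.05), while 70 probes were beyond 1.5-fold in that contrast and 1 in that of 1 and 4 against 2 and 3, and which arrays belong to which experiment is not given.

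For the number of probes changed, the 7 sign patterns of the 4 arrays that can be fitted are too few for a share under 0.05. The real pattern gave 2 probes and the highest other gave 0 (1 pattern as high, the real one). For probes at least 1.5-fold from 0 on all 4 arrays, 8 patterns are likewise too few, and the real one gave 11 against 7 for the highest other (1 pattern as high).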

How the results depend on the processing

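Print-tip loess combined with another choice, the experiment term, the centred authors' ratios, and the settings for the median of the 12 mitochondrial genes were chosen after seeing the data. The number of probes changed, 2 in the report, was 4 with median foreground, 1 with median centring in place of loess, 0 with print-tip loess, 9 without the dye term, 11 at an adjusted p below 0.1, and 15 with the authors' ratios (0 once centred). Taking arrays 1 with 2 and 3 with 4 as dye swaps gave 10, and 1 with 4 and 2 with 3 gave 41; a term for arrays 1 and 2 against 3 and 4, which leaves the same error contrast, gave 41. With print-tip loess, the first pairing gave 0, the second 299 (140 higher, 159 lower), and no dye term gave 0. If arrays 1 and 2 share extracts, the 41 and 299 leave the spread between experiments out of the error. Leaving out 1 array gave 0 to 10 (0 without array 1 or 3, 4 without 2, 10 without 4), where n is 3 and 1 orientation has a lone array. With print-tip loess 5522.1 stood at 1.69 ± 0.09 (adjusted p = 0.0770) and 12102.2 at 1.73 ± 0.12 (adjusted p = 0.105); the call ended though the SE fell, as the prior degrees of freedom went from 4.27 to 2.82. Over all alternatives the log2 fold change was 1.41 to 1.86 for 5522.1 and 1.45 to 1.88 for 12102.2, with adjusted p from 1.80e-08 to 0.273 and from 1.59e-08 to 0.502. The lowest values came from the authors' uncentred ratios, where the prior degrees of freedom were infinite and all probes shared the same SE (0.277). The 15 calls with those ratios rest on that shared SE and are not stronger evidence. The count at least 1.5-fold on all arrays (11) was 5 at 2-fold, and 11 to 45 without 1 array (45 without 1, 10 higher and 35 lower; 21 without 4, 14 and 7). Probes with a dye effect (0) were 3 with the authors' ratios and 0 without any 1 array. The mean array correlation (0.040) turned to −0.0096 with the authors' ratios and was 0.188 with print-tip loess. The median of the 12 mitochondrial genes stayed below 0, from −0.48 to −0.20; at −0.42 it was not past the threshold with an estimated correlation (p = 0.0783). Cox 2, NAD3 and NAD4 turned to 0.0914, 0.0919 and 0.0665 with the authors' ratios, which lack centring, and all 12 lay below 0 once centred; NAD3 ranged from −0.22 to 0.056 without 1 array (0.056 without array 1). COB and COX1 (adjusted p = 0.0211 and 0.0457) and probes 1222.2 and 14364.1 (both 0.0117) passed with arrays 1 with 4 and 2 with 3 paired; with print-tip loess too, 7 mitochondrial genes and 1222.2 passed, and 14364.1 did not (0.0884). With arrays 1 with 2 and 3 with 4 paired 1222.2 passed (0.0486), and without the dye term 14364.1 did (0.0350). The cause of the other moves was not tested. No gene list was matched with names compared as written, so alternatives for gene lists and the 12 fixed genes were not run. Median signal over background was lowest in Cy3 on array 3, at 2.99.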

Other observations

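The choice of CandidaDB numbers to order the probes, the test of neighbouring print positions, and leaving the run of 3 out of each test were chosen only after the run was seen. Of the 8 probes at least 1.5-fold higher on all 4 arrays, 3 had consecutive CandidaDB numbers, beginning with that of 12102.2, the one among them that passed the adjusted threshold. They were printed in 3 different blocks, stood 3.34- to 8.68-fold higher in C7-exposed cells, and had log2 ratios of at least 1.26 on every array. Because the order was chosen after this run was seen, its chance cannot be tested on these data. At the other end, the probe with the lowest mean carries the number just before that of 14364.1. What the order of these numbers follows, on the chromosomes or otherwise, is not given in the sources used here.

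Whether consecutive numbers move alike beyond that run was tested without its 3 probes. Across 5042 pairs of consecutive numbers printed in different blocks, the C7 effects correlated at r = 0.035, slightly above the upper bound of the shuffled 95% range (0.028), and at 0.037 after a fit on brightness was removed (bound 0.027), which argues against a blemish within a block and against brightness as the whole cause. A candidate explanation of what remained is print position, since r was 0.099 for the 1587 pairs at like positions in their blocks (bound 0.050) and 0.0091 for the 3455 at different positions (bound 0.034). The dye effect, which has no biological source, likewise correlated at 0.062 over pairs in different blocks and at −0.029 over those at different positions, the run included. With the run, r was 0.102 over pairs in different blocks and 0.072 at different positions, so that most of it came from 3 probes. A tendency of consecutive numbers to respond alike was therefore not seen beyond the run itself at different print positions, and what the run's 3 probes share was not tested.

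The EFT3#1 control spots, printed in a dilution series, gave log2 ratios of C7-exposed over untreated cells of 0.92, 0.58, −0.40 and −0.65 on arrays 1 to 4, undiluted, and 1.10, 0.51, −0.44 and −0.63 at the highest dilution. The spots of the *Saccharomyces cerevisiae* control SCTEF1 gave 1.11, −0.04, −0.79 and −1.19. Over the tested probes, the contrast of arrays 1 and 2 against 3 and 4 had 1.77 times the variance of that of 1 and 4 against 2 and 3.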
